A study of Mus musculus with 10 samples.

How the data were processed

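Total RNA from the cerebral cortex of mice aged 18 days was sequenced after removal of ribosomal RNA with RNase H, and the cDNA was primed with random hexamers, per the labels' protocols. The 10 libraries fall into 2 genotype groups of 5, called Usp7 cKO (conditional knockout) and Usp7 WT here, and all animals were heterozygous for Trp53, per the labels. The labels speak of 5 pairs matched by litter and sex, of which 2 are male and 3 female, but no label used here names the pairs, so the labelled sex was the covariate and a block was an alternative. Each library is from a separate animal, per the labels.

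The gene levels are TPM (transcripts scaled by length and library total) per gene, made by the authors, per the file headers. The TPM table held 55487 genes once 287 repeated lines were counted 1 time, and each library then summed to 1000000. The exon bin values are raw read counts of DEXSeq counting bins, per the deposited file headers, for 458337 bins of 51612 genes. The intron values are raw counts of spliced reads in leafcutter clusters, per the deposited file headers, for 32135 introns in 10838 clusters. The bin table also holds the authors' DEXSeq results, a log2 fold change of exon usage and a p-value with its adjusted p-value for each bin, per the file headers. The submitters' processing notes name STAR 2.7.9a, Subread, featureCounts, SAMtools 1.10 and the genome build GRCm38, without saying which step each made. The counting strand, the gene lengths behind TPM and the models of DEXSeq and leafcutter are not given in the sources used here. Reads from a gene and an overlapping antisense gene can therefore not be told apart, and members of gene families with near-identical copies are uncertain. Every intron count of Usp7 WT replicate 1 was even, against 52.8 to 55.0% even counts in the other libraries, and its deposited total of 8358248 was halved to 4179124 before use. The column of Ensembl identifiers in the intron table matched the gene symbol beside it in 0.65% of introns and was not used. The authors' intron usage differences were not used either. Of the gene identifiers, 55227 matched the annotation of GRCm38, from which positions, biotypes and the class of each bin were taken.

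Bin counts summed to between 42628526 and 51797145 per library and the intron counts used to between 3388310 and 4367711. TPM keeps no depth. Small and structural RNAs took 19.3 to 28.8% of TPM, so a change in them shifts every other gene, and the rescaled TPM below was one of the alternatives. A count of 0 was given an upper limit of 3 counts of the total, and such limits cover counting error alone.

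Gene levels were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 0.5), with trend and robust empirical Bayes, for genes with a mean of at least 0.5 TPM over all 10 libraries. Changes are Usp7 cKO minus Usp7 WT on that scale, which understates the change of low genes, and SE is the moderated standard error. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and all tests were two-sided. Exon usage and intron usage were tested with edgeR 4.0.16 (glmQLFit and diffSpliceDGE) on the deposited counts, with TMM scaling. Bins needed a mean count of at least 10 and introns of at least 5, genes or clusters at least 2 such features, and a gene or cluster was called on its Simes p. A bin's or intron's change is its log2 change minus that of its gene or cluster. The overlap of both kinds of change was tested with Fisher's exact test, and a product of genotype and labelled sex was tested in limma. Single values per library were compared with an exact permutation test over the 252 regroupings of 5 against 5 (scipy 1.17.1), whose smallest two-sided p is 0.00794. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

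The 36 gene lists were written before the data were examined, as were the tests, the covariate, most alternatives and the rule for the genes named. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 36 lists, and camera with an estimated correlation and fry were run beside it. Some genes are shared between lists, such as Camk2a and Sv2b by glutamatergic and synaptic lists and Sesn2 by p53 targets and stress genes. Calls of such lists are therefore not separate evidence. The rule names Usp7, Neurod6, Trp53, Mdm2, Cdkn1a and Ppil4, and the 12 largest rises and 12 largest falls past the threshold with a mean of at least 1 TPM and a symbol not of the Gm, Rik or pseudogene form. It also takes up to 4 members per list with the smallest p. A few genes that the rule names are not reported here. For exon bins it names Usp7 and the 10 genes with the smallest Simes p, Usp7 among them, and for introns the 10 called clusters with the largest difference in share and any cluster of Usp7.

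The alternatives for genes were another pseudocount, other filters, TPM rescaled by median-of-ratios size factors, edgeR and DESeq2 1.42.0 on bin counts summed per gene, no covariate, a block, array weights and each library left out in turn. A read over several bins counts more than once in such sums. For exon bins and introns they were other count minimums, other scaling, limma's voom with diffSplice, no covariate, a block, bins of a single gene, a minimum difference in share and each library left out. The sum of receptor genes, the libraries left out for their sex, Xist as covariate, intron counts as deposited and a second block were chosen after the data were seen.

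Each step was tested on simulated data for the comparison of 5 against 5 with 200 changed features. At a true log2 change of 0.5 and 1, limma called 29.9% and 72.9% of the changed genes (27416 genes tested). At these sizes edgeR called 22.2% and 81.8% of the changed bins (225742 bins tested), and edgeR on gene counts called 52% and 84.7% (22986 genes), with DESeq2 at 56% and 79% (23012 genes). The interaction step called 17.2% at a log2 of 1 and 59.6% at 2 (27392 genes). For introns, edgeR called 13.5% at a log2 of 1 and 57.0% at 2 (29283 introns), sizes that replaced smaller ones after a first run had recovered few. It called 59 of the 178 changed clusters and 9 without a simulated change, and limma's voom with diffSplice called 69 and 5. Of single introns edgeR called 35 without a simulated change, 34.7% of the introns called, and voom with diffSplice 59 or 43.1%. The same values were 9 or 8% for exon bins in edgeR and 2 or 2% for genes in limma. A changed feature also shifts the share of its neighbours, which were scored as unchanged. The intron and bin values are therefore not rates of false calls. Of 35 random lists, camera called 0 with either correlation and fry 1, and each called the list made to rise (27580 genes). The simulated genes varied independently of each other. In the real lists the estimated inter-gene correlation reached 0.715 (oligodendrocyte and myelin markers), so the simulation does not give the error rate of the list tests here.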

Results

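USP7 is a deubiquitinase, an enzyme that removes ubiquitin from proteins such as MDM2, the ubiquitin ligase of p53. In the mice studied here, Nex-Cre, which is active in glutamatergic neurons of the forebrain, deleted Usp7 on a background heterozygous for Trp53. Total RNA was measured in the cerebral cortex at 18 days of age in 5 Usp7 cKO and 5 Usp7 WT animals, as TPM for 55487 genes, counts of 458337 exon bins and counts of 32135 introns. The comparison asks which genes differed in level and which differed in exon or intron usage between the genotypes. Neurod6, whose locus drives Cre in Nex-Cre mice, was also lower in Usp7 cKO (below). An effect of lower Neurod6, or of Cre if Usp7 WT animals lack it, cannot be told apart here from loss of Usp7. Exon bin counts summed to between 42628526 (Usp7 cKO replicate 1) and 51797145 (Usp7 cKO replicate 4), and the intron counts used to between 3388310 and 4367711. The first principal component of the gene levels held 26.3% of the variance and separated the genotypes, with scores of -41.6 to -20.3 in Usp7 WT and 19.98 to 50.9 in Usp7 cKO. The library identifiers in the bin table run in genotype order, all Usp7 cKO before all Usp7 WT, so an effect of library order cannot be told apart from genotype in any comparison here.

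The sex in the labels went against sex-linked transcripts in a pair of libraries. The library labelled Usp7 WT replicate 2, a female in the labels, held 0.0478 TPM of Xist, the RNA that silences 1 X chromosome in females. It held 22.8 TPM of the Y-linked helicase Ddx3y. The library labelled Usp7 cKO replicate 1, a male in the labels, held 116 TPM of Xist and 0.0523 TPM of Ddx3y. The other 8 libraries followed their labelled sex, so Xist was high in 2 Usp7 WT and 4 Usp7 cKO libraries.

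Usp7 itself was lower in every Usp7 cKO library. The gene (ENSMUSG00000022710) lies on chromosome 16, 8689595 to 8792308, minus strand, GRCm38. Its level was 53.9 ± 5.32 TPM (SD, n = 5) in Usp7 WT and 36.9 ± 3.96 TPM in Usp7 cKO (log2 change -0.54, SE 0.0766, limma adjusted p = 0.00131). Of the Usp7 cKO libraries 5 of 5 lay below all Usp7 WT libraries (exact permutation p = 0.00794, the smallest possible). The bin of coding exon 7 of 32 (8707638 to 8707746, 109 bp, transcript Usp7-207) took 2.53 ± 0.236% of the gene's bin counts in Usp7 WT and 1.03 ± 0.150% in Usp7 cKO (n = 5), a relative log2 change of -1.29 (edgeR adjusted p = 2.4e-18). The authors' deposited table gives -1.28 for this bin. The remaining Usp7 bins also decreased, from 147 ± 6.17 to 98.4 ± 8.89 CPM (counts scaled to library size; n = 5, exact permutation p = 0.00794). Spliced reads that join exon 6 to exon 8 (intron 8706729 to 8708859) numbered 14, 17, 22, 19 and 16 in the Usp7 cKO libraries, or 29.5 ± 4.99% of the cluster (n = 5). In Usp7 WT they were 0 of 1106 cluster reads, which allows a share of up to 0.271%, and the cluster was called (edgeR adjusted p = 1.32e-08). The 2 libraries with discordant sex followed their labelled genotype, with 14 such reads in the library labelled Usp7 cKO replicate 1 and 0 in the library labelled Usp7 WT replicate 2. The neighbouring exon 6 bin (8708859 to 8708947) was used less (log2 -0.64, adjusted p = 0.00217), and a retained-intron bin (8696920 to 8697475) was used more (log2 0.83, adjusted p = 5.49e-07).

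**Figure D1:**
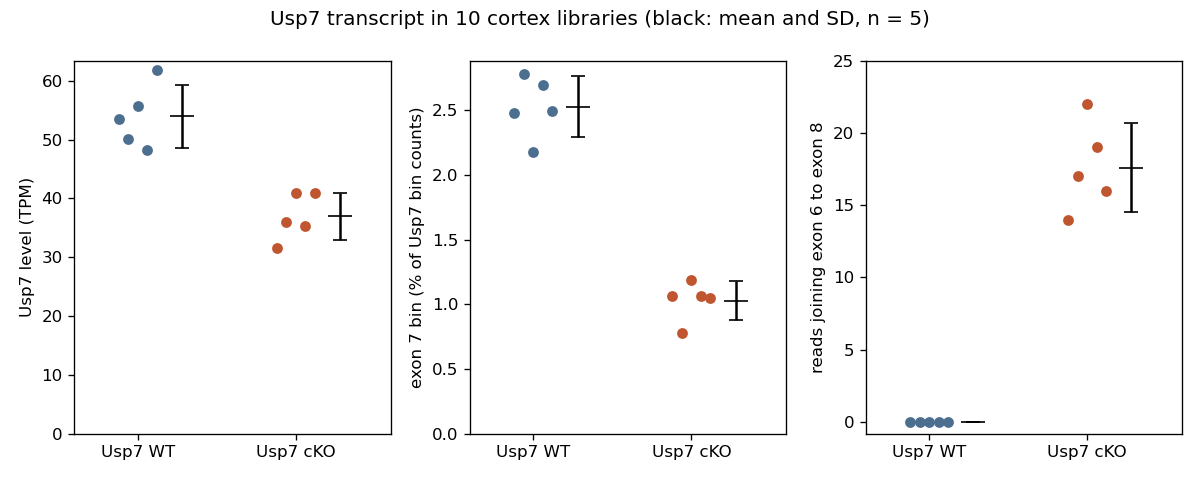
Usp7 level in TPM, the exon 7 bin as percent of Usp7 bin counts and the reads joining exon 6 to exon 8, in each of 5 Usp7 WT and 5 Usp7 cKO libraries (points) with mean and SD (black). All Usp7 cKO libraries lie below the Usp7 WT libraries in level and exon 7 share, and the 14 to 22 skipping reads of Usp7 cKO face 0 in Usp7 WT.

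Of the 27580 genes tested with limma, 3832 differed, 2544 higher and 1288 lower in Usp7 cKO. Most of the largest rises were in genes with little transcript in Usp7 WT cortex. Hmx1, a homeobox transcription factor, rose from 0.0568 ± 0.0570 to 17.1 ± 2.37 TPM (SD, n = 5; log2 4.98, SE 0.140, adjusted p = 2.92e-08). Prph, the intermediate filament peripherin of peripheral neurons, rose from 4.17 ± 0.695 to 96.8 ± 9.68 TPM (log2 4.39, SE 0.111, adjusted p = 2.59e-08). Gal, the neuropeptide galanin, rose from 0.457 to 17.5 TPM (log2 4.31) and Ecel1, an endopeptidase of neurons, from 3.48 to 61.6 TPM (log2 3.99). Zar1, a maternal factor of oocytes, rose from 0.505 to 16.0 TPM (log2 4.04), and the transcription factors Bhlhe23, Foxe1 and Mesp1 by 3.95, 3.67 and 3.59 on the log2 scale. Tnxb, an extracellular matrix tenascin, rose from 1.76 to 33.1 TPM (log2 3.85), and Cldn3, a tight junction claudin, from 1.504 to 25.5 TPM (log2 3.73). Lefty2, a secreted inhibitor of Nodal, rose from 2.31 to 30.3 TPM (log2 3.46). H2-Q2, of the class I histocompatibility family, rose from 0.839 to 15.8 TPM (log2 3.67), a value that is uncertain because family members have near-identical copies. Each of these 12 genes was higher in 5 of 5 Usp7 cKO libraries than in all Usp7 WT libraries. Chance gives such a separation with a two-sided exact permutation p of 0.00794 for a gene picked without regard to its values, but these were picked as the largest rises past the threshold, so their separation is no further evidence.

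The genes that fell most were of several kinds, and a shared function was not tested. Tnnc1, the calcium-binding troponin C of slow muscle, fell from 35.6 ± 5.52 to 8.78 ± 1.61 TPM (SD, n = 5; log2 -1.96, SE 0.129, adjusted p = 1.08e-05). Myl4, a myosin light chain, fell from 18.1 to 4.82 TPM (log2 -1.81). The protease inhibitor Serpinb8 fell from 9.66 to 1.99 TPM (log2 -2.05), the serine protease Tmprss7 from 5.87 to 1.33 TPM (log2 -1.79) and the keratin Krt80 from 1.94 to 0.285 TPM (log2 -1.63). Npsr1, the receptor of neuropeptide S, fell from 1.71 to 0.326 TPM (log2 -1.43) and Ighm, the constant part of immunoglobulin M, from 18.6 to 6.12 TPM (log2 -1.50). Trbj2-1, a joining segment of the T cell receptor beta locus, fell from 24.8 to 5.76 TPM (log2 -2.22, adjusted p = 0.00150). Each of these 8 was lower in 5 of 5 Usp7 cKO libraries. Of the other joining segments, Trbj1-4 fell from 7.49 to 1.31 TPM (log2 -2.69, adjusted p = 0.0291, 0.0156 to 0.0870 over its alternatives). Trbj2-4 fell from 6.03 to 0.761 TPM (log2 -2.52, adjusted p = 0.0323, 0.0157 to 0.138 over its alternatives). Trbj1-7 was listed at 0 in all 5 Usp7 cKO libraries and in Usp7 WT replicates 3 and 4, and held 5.43, 4.98 and 3.06 TPM in Usp7 WT replicates 1, 2 and 5 (adjusted p = 0.0391, 0.0255 to 0.0997 over its alternatives). Each of these 3 calls was lost without both libraries of discordant sex and with Xist as covariate. The Trbj1-4 call was also lost without Usp7 WT replicate 1, 3, 4 or 5 or Usp7 cKO replicate 1, 2 or 3 (log2 -2.68 to -2.18). That of Trbj2-4 was lost without Usp7 WT replicate 1, 2, 3 or 4 or Usp7 cKO replicate 1, 2 or 4 (log2 -2.56 to -2.04), and that of Trbj1-7 without Usp7 WT replicate 1, 2 or 5 or Usp7 cKO replicate 2, 3 or 5 (log2 -1.92 to -1.71). The Trbj1-7 call was also lost without the sex covariate (log2 -1.97) and at a pseudocount of 0.1 (log2 -3.29).

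The balance of higher and lower calls depended on scaling. Higher genes made up 66.4% of the calls on TPM as deposited, where the median change of all genes was 0.06, and 46.8% of 5648 calls after rescaling by median-of-ratios size factors, where it was 0.01. After rescaling 3617 of the 3832 calls were kept, all in the same direction. On bin counts summed per gene, edgeR called 6548 genes, 50.3% of them higher, and DESeq2 6589, 46.3% of them higher. Without the 2 libraries of discordant sex, a choice made after the data were seen, limma called 2183 genes, 60.2% of them higher. With Xist as covariate, also chosen after the data were seen, it called 3016 genes, 1688 higher and 1328 lower (56% higher).

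Neurod6, the neuronal transcription factor also called Nex whose locus drives Cre in Nex-Cre mice, fell from 52.1 ± 1.97 to 24.2 ± 2.45 TPM (SD, n = 5; log2 -1.10, SE 0.0727, adjusted p = 1.11e-05). Cdkn1a, the p53 target and cell cycle inhibitor p21, rose from 17.8 ± 1.30 to 36.7 ± 3.95 TPM (log2 1.02, SE 0.0821, adjusted p = 3.71e-05). Trp53 was 12.5 ± 1.42 and 12.6 ± 1.96 TPM (log2 0.00, SE 0.0929, adjusted p = 0.990) in Usp7 WT and Usp7 cKO. In the same order Mdm2 was 24.4 ± 2.59 and 23.8 ± 1.99 TPM (log2 -0.03, SE 0.0816, adjusted p = 0.827), and the spliceosomal isomerase Ppil4 16.6 ± 1.87 and 16.2 ± 0.877 TPM (log2 -0.03, SE 0.0811, adjusted p = 0.866). Of 38 p53 target genes, 14 rose and 5 fell (17 and 5 adjusted over the list alone). Pmaip1 and Bbc3, which encode the death-promoting proteins NOXA and PUMA, rose from 1.42 to 8.51 and from 14.6 to 25.2 TPM (log2 2.26 and 0.78), and Phlda3, an inhibitor of AKT, from 45.2 to 86.5 TPM (log2 0.94). The list as a whole was called (camera, adjusted p = 0.0406, and adjusted p = 0.942 with an estimated correlation). That call was lost without Usp7 WT replicate 3 (adjusted p = 0.0639), without Usp7 cKO replicate 1 (0.0928) and without both libraries of discordant sex (0.0740). Its adjusted p ran from 0.0210 to 0.942 over its alternatives.

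Synaptic genes, glutamatergic neuron markers and immediate early genes were among the lists that camera called lower. Of 29 glutamatergic neuron markers 14 fell and 1 rose (14 and 2 adjusted over the list alone; camera adjusted p = 3.65e-08, and adjusted p = 0.459 with an estimated correlation). Neurod6, whose locus drives Cre, is counted among the 14 that fell. Nrgn, the postsynaptic calmodulin-binding protein neurogranin, fell from 4640 ± 396 to 2391 ± 233 TPM (SD, n = 5; log2 -0.96, adjusted p = 3.89e-05). The pentraxin Nptx1 fell from 261 to 183 TPM (log2 -0.51), while the Wnt pathway activator Rspo1 rose from 7.38 to 34.8 TPM (log2 2.16). Of 36 presynaptic genes 19 fell and 1 rose (24 and 3 adjusted over the list alone; camera adjusted p = 2.2e-13, and adjusted p = 0.576 with an estimated correlation). Among them the complexin Cplx3 fell from 22.7 to 7.50 TPM (log2 -1.53) and the active zone protein Rims1 from 295 to 189 TPM (log2 -0.64). The vesicle protein Syn1 fell from 939 to 736 TPM (log2 -0.35) and the rabphilin Rph3a from 420 to 314 TPM (log2 -0.42). Of 37 postsynaptic density genes 18 fell and 2 rose (23 and 2 adjusted over the list alone; camera adjusted p = 4.23e-13, and adjusted p = 0.576 with an estimated correlation). The scaffold Homer1 fell from 78.9 to 43.8 TPM (log2 -0.84), Dlg1 and Dlg2 each by 0.37 and Cnksr2 by 0.43 on the log2 scale. Of 26 immediate early genes, which respond to neuronal activity, 6 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00105, and adjusted p = 0.848 with an estimated correlation). Those that fell included Egr3 (log2 -0.58), Ier5 (log2 -0.65) and Bdnf (log2 -0.45). Homer1 is on this list as well as on the postsynaptic one.

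Ion channel and receptor genes moved both ways. Of 40 voltage-gated potassium and sodium channels 14 fell and 3 rose (20 and 4 adjusted over the list alone; camera adjusted p = 1.02e-06, and adjusted p = 0.576 with an estimated correlation). Kcnv1 fell from 71.2 to 39.4 TPM (log2 -0.85). The modulatory subunit Kcns1 rose from 33.0 to 58.7 TPM (log2 0.82) and Kcnh2 from 27.1 to 37.1 TPM (log2 0.45). Of 21 GABA and glycine receptor genes 9 fell and 4 rose (9 and 4 adjusted over the list alone; camera adjusted p = 0.000663, and adjusted p = 0.576 with an estimated correlation). Gabrb2 fell from 107 to 81.3 TPM (log2 -0.39), while Gabre rose from 0.310 to 1.34 TPM (log2 1.19). Gabre reached the minimum mean only through Usp7 cKO, so its direction was fixed in advance. Of 35 glutamate receptor genes 9 fell and 4 rose (12 and 6 adjusted over the list alone; camera adjusted p = 0.00693, and adjusted p = 0.848 with an estimated correlation). The AMPA receptor subunit Gria3 fell (log2 -0.39), as did the metabotropic receptor Grm3 (log2 -0.32). The NMDA receptor subunit Grin2d rose from 20.5 to 36.6 TPM (log2 0.82) and the kainate receptor subunit Grik4 from 22.7 to 34.0 TPM (log2 0.57). Of 57 axon guidance and adhesion genes 12 fell and 9 rose (18 and 13 adjusted over the list alone; camera adjusted p = 0.0411, and adjusted p = 0.942 with an estimated correlation). The semaphorin Sema3a fell from 9.56 to 5.81 TPM (log2 -0.67) and the contactin Cntn4 by 0.37 on the log2 scale, while Sema3f rose from 11.8 to 25.2 TPM (log2 1.05) and the ephrin Efnb3 from 80.7 to 140 TPM (log2 0.80). The axon guidance call was lost in fry (adjusted p = 0.63). It was also lost without Usp7 WT replicate 3 (adjusted p = 0.0543) or Usp7 cKO replicates 2, 4 or 5 (0.0512, 0.0970 and 0.0524). Its adjusted p ran from 0.0178 to 0.942 over its alternatives.

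Markers of other cell types split by type. Of 22 microglia markers 17 fell and 0 rose (19 and 0 adjusted over the list alone; camera adjusted p = 8.79e-19, and adjusted p = 0.355 with an estimated correlation). The receptor Csf1r, on which microglia depend, fell from 60.1 ± 1.75 to 42.5 ± 3.23 TPM (SD, n = 5; log2 -0.50, adjusted p = 0.000179). The microglial membrane protein Tmem119 fell from 26.9 to 16.3 TPM (log2 -0.70), cathepsin S (Ctss) from 52.6 to 32.3 TPM (log2 -0.69) and Selplg by 0.62 on the log2 scale. Beside them, 5 of 22 interferon response genes fell and 3 rose (14 and 3 adjusted over the list alone; camera adjusted p = 0.000583, and adjusted p = 0.745 with an estimated correlation). The 3 that rose act in antigen presentation: H2-D1 from 33.4 to 67.2 TPM (log2 0.996), H2-K1 from 9.71 to 17.9 TPM (log2 0.85), both uncertain for their near-identical family members, and the peptide transporter Tap1 from 1.43 to 2.75 TPM (log2 0.75). Of 16 oligodendrocyte precursor markers 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.848 with an estimated correlation). C1ql1 rose from 31.5 to 70.0 TPM (log2 1.14) and Sapcd2 from 2.68 to 4.87 TPM (log2 0.76). The precursor call was lost after rescaling (adjusted p = 0.0622), without both libraries of discordant sex (0.0639) and with Xist as covariate (0.0563), in a range of 0.00621 to 0.848. Of 21 striatal, hippocampal and thalamic markers 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.576 with an estimated correlation). Among these the desmosomal protein Dsp, a marker of the dentate gyrus, rose from 0.319 to 3.99 TPM (log2 2.42) and the copine Cpne7 from 20.4 to 55.8 TPM (log2 1.41). Dsp reached the minimum mean only through Usp7 cKO, so its direction was fixed in advance. The kinase Prkcd rose from 7.42 to 15.7 TPM (log2 1.03) and the calcium-binding calretinin gene Calb2 from 20.2 to 31.3 TPM (log2 0.62). Calb2 is on the list of GABAergic neuron markers too, so its rise is not particular to these regions.

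Lists of the remaining cell types were not called by camera. Of 20 astrocyte markers 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.466), among them the sodium pump subunit Atp1b2, from 306 to 385 TPM (log2 0.33). Of 28 GABAergic neuron markers 3 rose and 3 fell (7 and 4 adjusted over the list alone; adjusted p = 0.386), and Nos1, the neuronal nitric oxide synthase, rose from 17.8 to 25.8 TPM (log2 0.52). Of 19 reactive glia genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.492). The complement gene C4b rose from 7.50 to 16.9 TPM (log2 1.11), uncertain for its near-identical neighbour C4a, and Cd44 fell from 2.75 to 1.41 TPM (log2 -0.77). None of 24 oligodendrocyte and myelin markers, 25 endothelial, mural and meningeal markers, 9 blood cell markers and 9 sex-chromosome genes passed in limma, also 0 adjusted over the list alone (camera adjusted p = 0.667, 0.729, 0.723 and 0.678). Of 11 choroid plexus and ependymal markers 1 rose (2 adjusted over the list alone; adjusted p = 0.723). The oligodendrocyte list was called lower without Usp7 WT replicate 1 (adjusted p = 0.0428, 0.0428 to 0.992 over its alternatives). Its median change was 0.01 while camera's direction was down, and the sex-chromosome genes had a median of 0.08 and a mean of -0.39. The labelled sex in the model was discordant in 2 libraries, which widens the error of sex-linked genes. Their lack of calls therefore does not show equal levels, and Xist was high in 2 Usp7 WT and 4 Usp7 cKO libraries.

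Camera called cell cycle genes and the tested part of the developmental genes silenced by Polycomb higher, and the list of Polycomb subunits was not called. Of 27 cell cycle genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.00250, and adjusted p = 0.716 with an estimated correlation). Among them the replication helicase subunits Mcm6 rose from 4.52 to 8.83 TPM (log2 0.90) and Mcm2 from 2.30 to 3.69 TPM (log2 0.57). Of 68 developmental transcription factors kept silent by Polycomb 17 were expressed highly enough to be tested. Of these 5 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.607 with an estimated correlation). Pax2, a regulator of hindbrain and kidney development, rose from 0.157 to 1.08 TPM (log2 1.27) and Foxf1, a regulator of lung and vessel development, from 0.735 to 2.40 TPM (log2 1.27). The list lost its call without Usp7 WT replicate 3 (adjusted p = 0.0639, in a range of 0.00525 to 0.607). Of the 5 that rose, En2 lost its own call with the block by sex, with Xist as covariate and without both libraries of discordant sex. Its call was also lost without any single library other than Usp7 WT replicate 2 (log2 0.64 to 0.86). Phox2a lost its call without both libraries of discordant sex (log2 1.05). Members of the list under 0.5 TPM in Usp7 WT, such as Pax2 and Phox2a (0.188 to 0.905 TPM), reach the minimum mean only through Usp7 cKO. The direction of such members is thus fixed in advance. Most of the 68 were not tested, so a rise of the whole class is not shown. Of 29 PRC1.1 and other Polycomb subunits 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.145). The PRC1.1 subunit Kdm2b rose from 12.3 to 17.7 TPM (log2 0.50), Bcorl1 from 19.5 to 25.98 TPM (log2 0.41) and the ubiquitin ligase Rnf2 from 18.7 to 23.7 TPM (log2 0.34), while Cbx6 fell from 222 to 178 TPM (log2 -0.32).

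By camera, which tests a list against the other genes, deubiquitinase genes and mitochondrially encoded genes were called lower, and proteasome and ubiquitin genes higher. Of 56 deubiquitinase genes 4 rose and 4 fell (5 and 4 adjusted over the list alone; camera, down, adjusted p = 0.0149, and adjusted p = 0.942 with an estimated correlation). Usp11 fell from 74.5 to 52.5 TPM (log2 -0.50) and Usp32 from 84.7 to 65.3 TPM (log2 -0.37), while Usp35 rose from 16.8 to 25.4 TPM (log2 0.58). The deubiquitinase call was lost in fry (adjusted p = 0.591) and without Usp7 WT replicate 3 (adjusted p = 0.0543), in a range of 0.000989 to 0.942. Of 37 proteasome and ubiquitin genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera, up, adjusted p = 0.0411, and adjusted p = 0.942 with an estimated correlation). The 1 that fell was Nfe2l1, the activator of proteasome genes (log2 -0.21). The proteasome call was lost after rescaling (adjusted p = 0.521) and in fry (0.274). It was also lost without Usp7 WT replicate 4 or 5 (0.407 and 0.114) or Usp7 cKO replicate 2 or 4 (0.0512 and 0.128). Its adjusted p ran from 0.000288 to 0.942. Of 26 USP7 partners and reported substrates 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.735, with a median of 0.01 against camera's direction of down). Besides Usp11, Magel2, which forms a ubiquitin ligase complex with USP7, rose from 2.04 to 4.54 TPM (log2 0.98), the chromatin ligase Uhrf1 from 1.66 to 3.01 TPM (log2 0.70) and Rnf220 from 62.1 to 76.3 TPM (log2 0.30). Of 15 mitochondrially encoded genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.00521, and adjusted p = 0.576 with an estimated correlation), with mt-Nd4 and mt-Co1 at log2 -0.20 and -0.17. The call of the mitochondrial list was lost in fry (adjusted p = 0.119) and with Xist as covariate (adjusted p = 0.0870), in a range of 0.000684 to 0.576. The calls of both genes were lost with Xist as covariate, and that of mt-Co1 also without both libraries of discordant sex. Of 50 nuclear oxidative phosphorylation genes 1 rose (0 adjusted over the list alone; camera, up, adjusted p = 0.0749). That list was called without Usp7 WT replicate 1, 2 or 3 (adjusted p = 0.0368, 0.0153 and 0.000584) and without Usp7 cKO replicate 5 (0.0497), as well as without both libraries of discordant sex (0.0328), in a range of 0.000584 to 0.942.

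Of 26 integrated stress and unfolded protein response genes 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.366). The pseudokinase Trib3 rose from 0.442 to 1.80 TPM (log2 1.26) and Sesn2 from 12.7 to 17.8 TPM (log2 0.48). Trib3 reached the minimum mean only through Usp7 cKO, so its direction was fixed in advance. Of 24 cholesterol synthesis genes 2 rose (2 adjusted over the list alone; adjusted p = 0.824, with a median of 0.01 against camera's direction of down). Among them was Tm7sf2, a sterol reductase, which rose from 12.8 to 18.6 TPM (log2 0.52). Of 54 clustered protocadherins, whose copies are alike and whose values are uncertain, 12 rose and 6 fell (15 and 8 adjusted over the list alone; adjusted p = 0.525), with Pcdhb5 at 7.85 and 17.4 TPM (log2 1.09) and Pcdhac2 at 61.8 and 51.0 TPM (log2 -0.28).

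Among the lists of splicing factors, the neuronal splicing regulators were called lower and the others were not called. Of 58 core spliceosome components 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.783, with a median of 0.02 against camera's direction of down). Of 40 SR and hnRNP splicing regulators 4 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.723). Of 10 spliceosomal peptidyl-prolyl isomerases 0 passed in limma, also 0 adjusted over the list alone (adjusted p = 0.691). Of 26 neuronal splicing regulators 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00711, and adjusted p = 0.881 with an estimated correlation). Rbfox3, the neuronal antigen NeuN, fell from 204 to 162 TPM (log2 -0.33), Rbfox1 from 278 to 220 TPM (log2 -0.33) and Khdrbs3 from 158 to 124 TPM (log2 -0.35). In all, camera called 19 of the 36 lists, 6 up and 13 down. With an estimated correlation 0 lists were called (smallest adjusted p = 0.355). Fry, which tests a list against no change, called 9 and did not call 10 of camera's 19. These were voltage-gated channels (adjusted p = 0.0758), GABA and glycine receptors (0.115), mitochondrially encoded genes (0.119) and immediate early genes (0.259). They also included interferon response and proteasome genes (0.274 each) and neuronal splicing regulators (0.31). The remaining ones were glutamate receptors (0.441), deubiquitinases (0.591) and axon guidance genes (0.63).

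**Figure D2:**
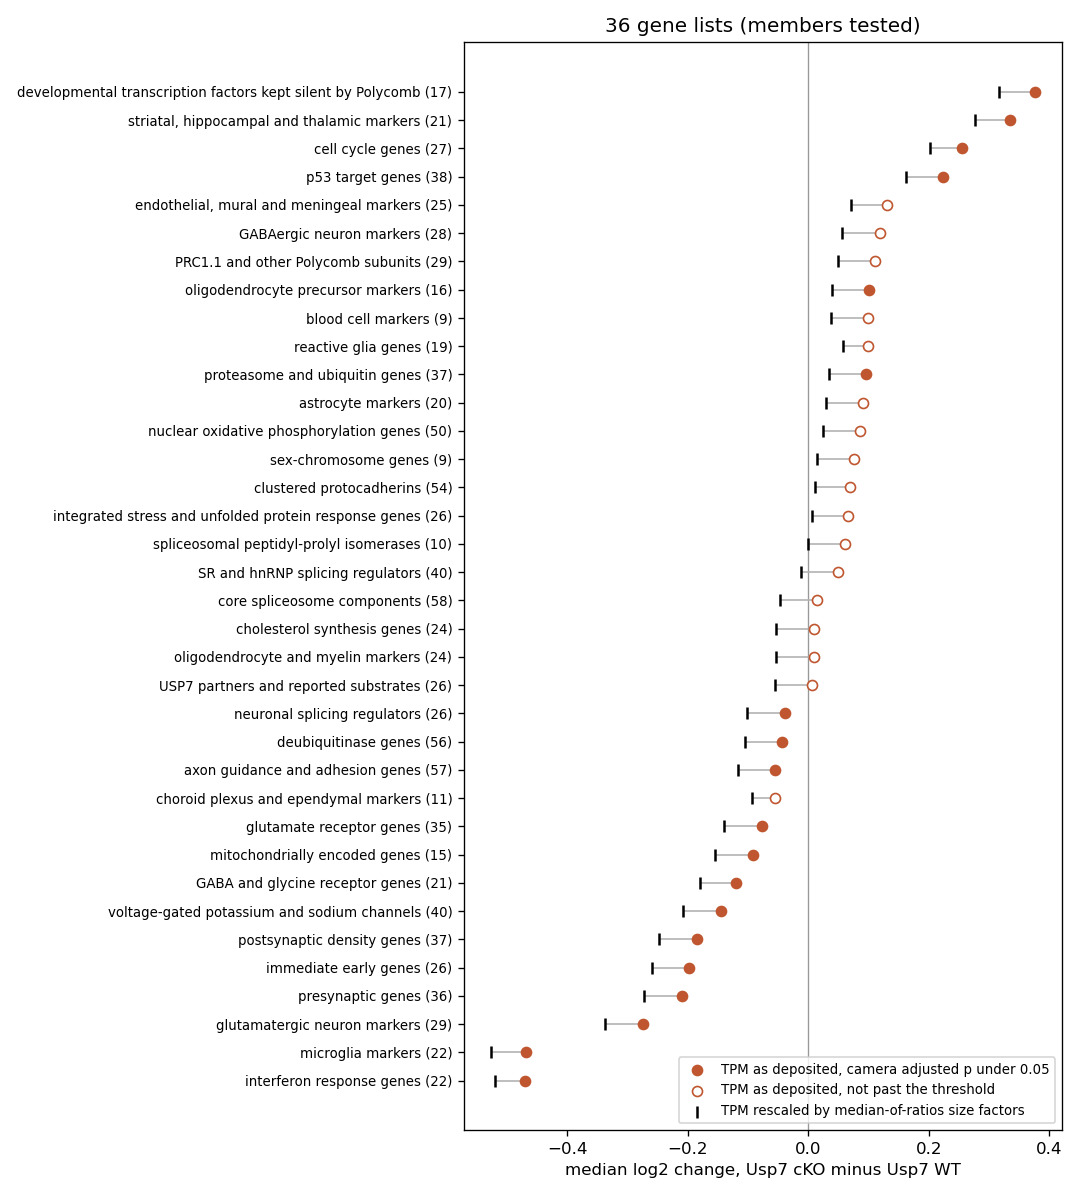
Median log2 change, Usp7 cKO minus Usp7 WT, of each of the 36 gene lists (members tested in brackets), on TPM as deposited (circles, filled where camera's adjusted p is under 0.05) and after rescaling by median-of-ratios size factors (black ticks). Microglia markers (-0.47) and interferon response genes (-0.47) lie lowest and developmental transcription factors (0.38) highest, and rescaling moves every list lower, past 0 for SR and hnRNP, core spliceosome, cholesterol, oligodendrocyte, isomerase and USP7 partner genes.

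Exon usage differed in 397 of 13954 genes tested with edgeR, by 980 of 228098 bins, of which 755 were used more and 225 less in Usp7 cKO. Retained-intron bins made up 38.3% of the bins used more (289 bins). They were 7.3% of the bins tested and 5.3% of those used less (12 bins). Total RNA also holds transcripts not yet spliced, so more use of retained-intron bins need not mean introns retained in mature RNA. Usage of exons and introns was measured in bulk cortex, so a change in it need not be a change of splicing within a cell. Shifts in the mix of cells or in transcript starts and ends were not separated from it. Bins of 5' UTR made up 27.6% of those used less (62 bins), 12.5% of those used more (94 bins) and 9.0% of those tested. Coding bins made up 26.5% of those used more, 38.2% of those used less and 73.5% of those tested. Abr used a 5' UTR bin more (chromosome 11, 76622177 to 76623558, GRCm38), with 0.204 ± 0.0199% of the gene's counts in Usp7 WT and 0.534 ± 0.0643% in Usp7 cKO (SD, n = 5; relative log2 1.38, adjusted p = 8.91e-28). Dlg4, the postsynaptic scaffold PSD-95, used a 3' UTR bin more (chromosome 11, 70045533 to 70047522), with 0.270 and 0.686% (log2 1.34). Mef2c, a neuronal transcription factor, used a 5' UTR bin less (chromosome 13, 83520385 to 83520480), with 0.165 and 0.0329% (log2 -2.31), and Pth1r, the parathyroid hormone receptor, likewise (chromosome 9, 110742346 to 110742719), with 10.5 and 2.94% (log2 -1.85). Yjefn3 used a non-coding bin more, with 3.98 and 14.1% (log2 1.85), and Dido1 a coding bin, with 7.05 and 12.2% (log2 0.79). Bins used more were also found in Epb41l1 (5' UTR, log2 1.02), Shroom2 (coding, log2 0.98) and Rabl6 (non-coding, log2 1.04).

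Over whole libraries, retained-intron bins held 2.34 ± 0.183% of the bin counts of 9029 genes that have them in Usp7 WT and 2.68 ± 0.266% in Usp7 cKO (n = 5, exact permutation p = 0.0476, adjusted p = 0.119 over 10 such shares). Spliced reads outside annotated introns were 8.97 ± 0.153% and 9.46 ± 0.349% (n = 5, exact permutation p = 0.0159, adjusted p = 0.119), so neither share passed. An adjusted p under 0.05 was given to 1561 bins of 887 genes in the authors' deposited table, and 642 of the 980 bins called here were among them. Across bins, which are not independent replicates, the relative changes correlated at 0.964 with the authors' deposited log2 folds. Without both libraries of discordant sex 215 genes and 510 bins were called, 364 of the bins used more and 146 less. With Xist as covariate 157 genes and 439 bins were called, 282 of the bins used more and 157 less, so the lean toward more use was smaller there. Without Usp7 WT replicate 1, Usp7 WT replicate 2 or Usp7 cKO replicate 5 the genes numbered 246, 257 and 239, and without Usp7 WT replicate 1 or Usp7 cKO replicate 5 the bins 628 and 574.

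**Figure D3:**
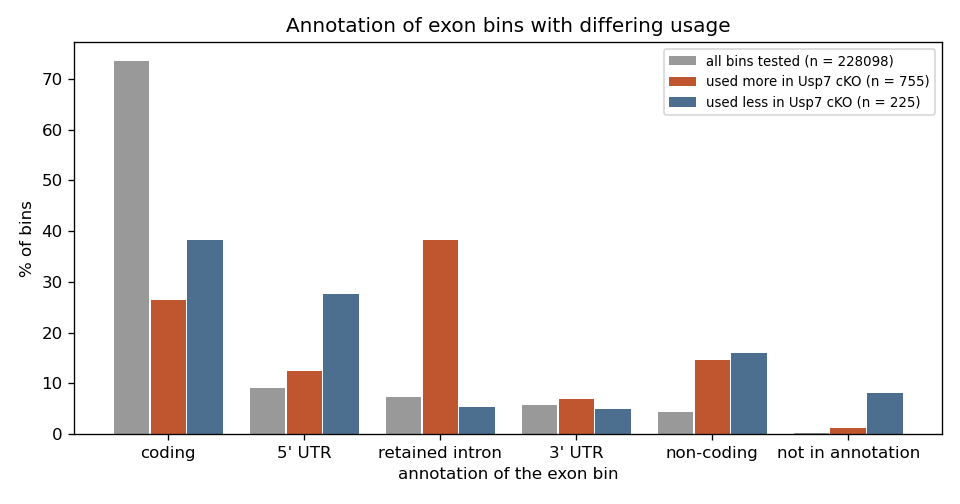
Share of bins in each annotation class, in percent, among the 228098 exon bins tested (grey), the 755 used more (red) and the 225 used less (blue) in Usp7 cKO. Retained-intron bins make up 38.3% of those used more and 7.3% of all tested.

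Intron usage differed in 23 of 10441 clusters tested with edgeR, by 36 introns, 18 used more and 18 less. In simulated counts of these libraries 34.7% of the introns called had no simulated change, so single introns are less certain than their clusters. Neighbours of a changed intron were scored as unchanged there, though their share shifts too, so 34.7% is not a rate of false calls. Whole clusters were also called without a simulated change, 9 beside 59 with one. Neighbours do not account for these, so the 23 clusters may hold false calls too. Apart from Usp7, an intron of D430041D05Rik (chromosome 2, 104255570 to 104409929, GRCm38) took 22.5 ± 3.22% of its cluster in Usp7 WT and 44.7 ± 3.46% in Usp7 cKO (SD, n = 5; cluster adjusted p = 0.00165). An intron of Sun1, which links the nucleus to the cytoskeleton (chromosome 5, 139226885 to 139233471), took 22.6 ± 3.94% and 9.11 ± 1.39% (cluster adjusted p = 0.00144). An intron of Cacnb3, a calcium channel subunit (chromosome 15, 98632520 to 98639488), took 15.9 ± 2.05% and 33.9 ± 3.84% (cluster adjusted p = 0.00539). In Rtn4, which encodes the growth inhibitor Nogo, an intron (chromosome 11, 29718882 to 29733633) took 42.3 ± 6.78% and 24.0 ± 5.72% (cluster adjusted p = 0.0117). In Olfm2 an intron with a 5' splice site outside the annotation (chromosome 9, 20675723 to 20746171) took 18.9 ± 2.7% and 38.7 ± 2.48% (cluster adjusted p = 0.0201). In the Rac activator Tiam1 an intron (chromosome 16, 89813127 to 89817961) took 14.8 ± 2.21% and 3.63 ± 2.57% (cluster adjusted p = 0.0103). In Epb41l1, which also differed in exon usage, an intron (chromosome 2, 156476006 to 156493904) took 70.7 ± 2.31% and 54.8 ± 4.56% (cluster adjusted p = 0.0307; the intron alone, adjusted p = 0.815). A gene-less intron (chromosome 16, 76800692 to 76877397) took 36.8% in Usp7 WT replicate 4 and 73.9, 76.0 and 46.3% in Usp7 cKO replicates 2, 4 and 5, and 0.0349% or less in the other 6 libraries (cluster adjusted p = 0.00631). Another (chromosome 15, 100965374 to 100965463) took 21.1 ± 13.3% in Usp7 WT and 0.288 ± 0.461% in Usp7 cKO (cluster adjusted p = 0.0343).

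The 2 other clusters of Usp7, over its exons further upstream, were not called (adjusted p = 1). The call for the named intron was lost in Olfm2 without Usp7 WT replicate 1, 2 or 3 (log2 0.99, 0.98 and 0.98), Usp7 cKO replicate 2 or 5 (log2 0.997 each) or both libraries of discordant sex (log2 0.97). It was lost in Rtn4 without Usp7 WT replicate 2 (log2 -0.77) or Usp7 cKO replicate 2 or 5 (log2 -0.85 and -0.78). In Tiam1 it was lost without Usp7 WT replicate 3 (log2 -1.91), Usp7 cKO replicate 2, 4 or 5 (log2 -1.93, -1.95 and -1.90) or both libraries of discordant sex (log2 -2.02). The intron of Cacnb3 lost it without both libraries of discordant sex (log2 0.996), and the gene-less intron of chromosome 16 without Usp7 WT replicate 1, 2 or 5 (log2 2.97, 3.22 and 2.66). That of chromosome 15 lost it without Usp7 WT replicate 1 or 4 (log2 -5.90 and -5.88), Usp7 cKO replicate 2, 3 or 5 (log2 -6.42, -5.98 and -5.68) or both libraries of discordant sex (log2 -6.30). Beyond left-out libraries, the Olfm2 intron lost its call with Xist as covariate (log2 1.01), and the chromosome 15 intron with limma's voom and diffSplice (log2 -5.40). The chromosome 16 intron lost it with voom and diffSplice (log2 1.99), without the sex covariate (log2 1.67) and at a minimum mean count of 20 (log2 4.15). The count of 23 clusters moved by over 1.5 times without Usp7 WT replicate 1 (14) or 2 (15) or Usp7 cKO replicate 2 (13), 4 (14) or 5 (15), and limma's voom with diffSplice called 193 clusters, 17 of the 23 among them.

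Genes with a change in level and genes with a change in exon usage overlapped. Of 13934 genes tested for both, 154 were called in both, against 77.9 by chance (odds ratio 2.69, 95% interval 2.18 to 3.33, Fisher's exact test p = 3.76e-19). Among the 6967 genes at or above the median of the mean bin count the odds ratio was 2.596 (95% interval 2.065 to 3.256). Both kinds of call come from the same 10 libraries and genes are not independent, so these intervals and the p-value do not measure spread between animals. Of these 154 genes 50 were higher and the others lower in Usp7 cKO, and Usp7 was among the lower ones.

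The change by genotype differed between the labelled sexes in 2 of 27580 genes, with 776 at an unadjusted limma p under 0.05. Mir339, a microRNA gene, had means of 3.47 and 8.00 TPM in labelled females and 4.95 and 0 TPM in labelled males, for Usp7 WT and Usp7 cKO (log2 difference, male minus female, -4.50, SE 0.375, adjusted p = 0.00765). The unnamed gene Gm23190, given because the count is small and so chosen after its values were seen, had 0 and 1.99 TPM in labelled females and 1.87 and 0 TPM in labelled males (log2 difference -4.56, SE 0.327, adjusted p = 0.00402). Labelled males were 2 per genotype, and the sex of 2 libraries was discordant. Without those libraries 0 genes were called in limma (727 at an unadjusted p under 0.05), and without Usp7 WT replicate 4 also 0 (902). Without Usp7 cKO replicate 1 there was 1, without Usp7 cKO replicate 4 there were 9 and without Usp7 cKO replicate 5 there were 3.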

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

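The tests of the discordant sex were chosen after the levels of Xist and the Y-linked genes were seen. Of 408 groups of 5 libraries examined for a library far from the others, 28 had one, against 20.4 that chance gives at about 1 in 20.

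Usp7 WT replicate 4 stood apart in 9 of them. It was the lowest Usp7 WT library for Zar1 (0.358 TPM, the next 0.512), Serpinb8 (7.12 TPM, the next 9.78) and Myl4 (13.7 TPM, the next 18.1). The same held for Kcns1 (29.7 TPM, the next 33.2) and the Rabl6 exon bin (0.750% of the gene's counts, the next 1.21%). It was the highest for the haemoglobin genes Hbb-bs (292.0 TPM, the next 237) and Hba-a1 (256 TPM, the next 197), for Cpne7 (25.4 TPM, the next 19.7) and for the gene-less intron of chromosome 16 (36.8% of its cluster, the next 0.0349%).

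Usp7 cKO replicate 3 stood apart in 6, as the highest Usp7 cKO library for Gfap, the astrocyte filament (133 TPM, the next 99.5), and Cox5b (328 TPM, the next 302). It was also the highest for Bbc3 (28.3 TPM, the next 24.9), Psmb3 (62.1 TPM, the next 57.6), Dsp (6.32 TPM, the next 3.79) and the Tiam1 intron (8.22% of its cluster, the next 2.89%). Usp7 cKO replicate 5 was the highest for Efnb3 (153 TPM, the next 138) and Calb2 (34.98 TPM, the next 31.0) and the lowest for Ier5 (43.5 TPM, the next 53.9). Usp7 WT replicate 5 was the highest for Kdm2b (14.3 TPM, the next 12.3) and the Epb41l1 intron (74.8% of its cluster, the next 70.2%). The library labelled Usp7 cKO replicate 1 was the highest for Slc4a1, the anion exchanger of red blood cells (1.53 TPM, the next 0.608), and for the Rtn4 intron (33.9%, the next 23.0%). Usp7 WT replicate 3 was the highest for Phox2a (0.655 TPM, the next 0.139) and Usp7 WT replicate 1 for the D430041D05Rik intron (28.05%, the next 22.1%).

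The change by genotype differed between the labelled sexes, by the interaction test in limma, in Mir339 (log2 difference -4.50) and in Gm23190 (log2 difference -4.56).

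Sex-linked genes set Usp7 cKO replicate 4 apart, as the highest of its group for the Y-linked genes Kdm5d (7.29 TPM, the next 0.00896) and Uty (6.62 TPM, the next 0.0486). It was the lowest for Xist (0.223 TPM, the next 96.5) and for Eif2s3x (38.5 TPM, the next 53.8). It is thus the lone Usp7 cKO library with Y-linked transcripts, although the labels give 2 males in that group. An exchange of the library labelled Usp7 WT replicate 2 with the library labelled Usp7 cKO replicate 1 is argued against by the Usp7 junction from exon 6 to exon 8, which had 14 reads in the latter and 0 in the former. Mixing of libraries of both sexes is argued against too, since Ddx3y in the library labelled Usp7 cKO replicate 1 was 0.249% of the level of the libraries that express it, and Xist in the library labelled Usp7 WT replicate 2 was 0.0417% of the level elsewhere. A candidate explanation that stays open is a wrong sex in the labels of these 2 libraries, and an exchange with another animal of the same genotype would look alike. The sex of the animals as a biological difference was not tested further.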

How the results depend on the processing

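The settings without the libraries of discordant sex, with Xist as covariate, with intron counts as deposited and with the title number alone as block were chosen after the data were seen. Of 229 single genes, bins, introns and lists, 55 lost a call in at least 1 alternative and 15 reversed in at least 1. With 1 library left out, 2108 such values kept direction and side of the threshold, 134 lost the call, 21 gained it and 25 reversed. In the other alternatives 2074 kept them, 114 lost the call, 60 gained it and 22 reversed. Of the 3832 genes called, 3793 were tested with each library left out in turn and 2329 called each time. In all 13 other settings 3165 were tested, 3244 of the calls passing the minimum of 2 TPM, and 1563 were called. Over all settings together 1495 of 3165 were called (917 higher, 578 lower). Unless the setting itself removes samples or features, the cause was not tested.

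Counts moved as follows. Genes numbered 6548 in edgeR, 6589 in DESeq2 and 2183 without the discordant libraries, and 2789 to 3586 with 1 library left out. Called lists numbered 0 with an estimated correlation and 9 with fry. Genes by exon usage numbered 239 to 368 and bins 574 to 901 with 1 library left out, 215 and 510 without the discordant libraries and 157 and 439 with Xist. Intron clusters numbered 13 to 25 with 1 library left out and 193 with voom and diffSplice. Interaction genes numbered 0 to 9 with 1 library left out, 1 at a minimum of 2 TPM, 0 without the discordant libraries and 0 with Xist.

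Values that changed sign were as follows. Trp53 had a log2 change of -0.058 rescaled, -0.080 in edgeR, -0.092 in DESeq2, -0.012 with array weights, -0.0625 without the discordant libraries, -0.11 with Xist and -0.055 to 0.043 with 1 library left out. Mdm2 ranged from -0.0634 to 0.0230 and Ppil4 from -0.0775 to 0.0247 with 1 library left out. Ppil4 was 0.0052 with array weights, and Kdm5d, at -1.63 with the labelled sex, was 0.029 with Xist. Of the Usp7 introns, that at 8706729 to 8707638 moved from -0.40 to 0.10 with a minimum of 20 reads, and those at 8712192 to 8715745 and 8710177 to 8711994 ranged from -0.0630 to 0.25 and from -0.019 to 0.0012. The direction of the list test reversed, without a call, for cholesterol genes (adjusted p 0.582 in fry, 0.881 without the discordant libraries, 0.923 with Xist, 0.524 to 0.980 with 1 library left out), choroid markers (0.929 in fry, 0.276 to 0.941) and core spliceosome genes (0.630 in fry, 0.407 to 0.888). It also reversed for endothelial markers (0.707 without the discordant libraries, 0.615 with Xist, 0.256 to 0.866) and oligodendrocyte markers (0.929 in fry, 0.992 without the discordant libraries, 0.0428 to 0.862). The same held for sex-chromosome genes (0.976 with Xist) and SR and hnRNP genes (0.721 rescaled, 0.918 with Xist, 0.222 to 0.980). For USP7 partners the direction differed in fry alone (0.582), which tests a list against no change.

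The number at the end of the titles was used as a block within each labelled sex. The 9 pairs with the same number, 7 of them also of the same labelled sex, correlated at -0.016 to 0.092 in their deviations. Pairs of different numbers correlated at -0.093 to 0.034. All these correlations are low, so the numbers were not taken as pairs. Yet the numbers are balanced between the genotypes within each labelled sex, as matched pairs would be, and all 10 libraries correlated best with a library of their own number, so whether they mark litters stays open. With that replicate block limma called 3654 genes, camera 19 lists and edgeR 427 genes by exon usage, 1083 bins and 19 intron clusters, and with the number alone as block limma called 4391 genes. Of the genes and introns named in the report, Trbj2-4 (log2 -2.52), Trbj1-7 (log2 -1.97), En2 (log2 0.78) and the chromosome 15 intron (log2 -6.20) were not called with the block by sex, nor Trbj1-7 with the number alone. TPM keeps no depth, and the introns with few reads limit what the cluster test can find.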

Other observations

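The groups of low genes, the chromosome regions and the tests of technical explanations below were chosen after the results were seen, as were the regroupings of the samples for genes and lists; those for exon usage and introns were set before.

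Many of the genes that rose were all but silent in Usp7 WT cortex. Of 901 tested genes with under 0.5 TPM in Usp7 WT, 206 rose in Usp7 cKO, 95 of them protein-coding, with a median log2 TPM ratio of 2.12, and 11 were listed at 0 in every Usp7 WT library. Those 11 were small RNAs, pseudogenes and other genes not annotated as protein-coding, with means of 1.15 to 2.6 TPM in Usp7 cKO. Because a mean of at least 0.5 TPM over all libraries was required, each of the 901 was above 0.5 TPM in Usp7 cKO by construction, and only the calls among them carry information. Besides Hmx1, Foxe1, Mesp1, Gal and Bhlhe23 they included Pou4f3, a transcription factor of hair cells (0.110 to 5.00 TPM), Onecut3 (0.113 to 4.29 TPM) and Gsc2 (0.132 to 3.62 TPM). They also included the growth factor Fgf3 (0.206 to 3.06 TPM) and the tumour suppressor Cdkn2a (0.352 to 1.26 TPM). In the other direction, 42 of 355 tested genes with under 0.5 TPM in Usp7 cKO fell, a set whose direction is fixed in the same way.

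Genes of the H2 region of chromosome 17 (33974659 to 37483552, GRCm38, 3.51 Mb), which holds the histocompatibility genes, were called higher in 25 of 152 cases (16.4%), against 9.2% of tested genes elsewhere, and 5 were called lower. The span was drawn after H2-Q2, H2-D1, H2-K1 and Tap1 were seen to rise, and these are counted in it, so the difference is given with no test. Reads shared between family members leave single genes uncertain. Genes within 10 Mb of the altered loci did not stand out: 37 of 244 near Usp7 and 21 of 170 near Neurod6 were called, together 14% against 13.9% elsewhere (Fisher's exact test p = 0.943).

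Several technical explanations were weighed for the rise of near-silent genes. Background reads from DNA or other RNA are argued against by the summed TPM of 2003 olfactory and vomeronasal receptor genes, whose log2 ratio was -0.142 (95% upper bound 0.244). Scaling by abundant small RNAs is argued against because 100% of the 206 genes were called higher after rescaling. A one-sided effect of the expression minimum is argued against because, with no minimum and after rescaling, 391 of 16934 genes under 0.5 TPM in Usp7 WT rose and 126 of 16229 under 0.5 TPM in Usp7 cKO fell (exact binomial p = 1.36e-32 over genes, which are not independent). Tissue from outside the cortex stays open, since median changes were 0.162 for thalamic, 0.513 for striatal and 0.611 for hippocampal markers of at least 10 TPM, neither alike nor all near 0. A hypothesis is that loss of Usp7 may lift the silencing of such genes in the neurons that lack it; these bulk data hold no test of that.

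The fall of microglia markers was weighed in the same way. Scaling is argued against, since their median change after rescaling was -0.526. A lower share of non-neuronal tissue is argued against by the astrocyte, oligodendrocyte, precursor and vascular markers, whose lowest median change was 0.00912. Fewer microglia with an unchanged profile cannot be told apart from a changed profile: the SD of the markers' changes was 1.59 times their mean SE (95% bootstrap interval 1.1 to 2.04 over markers), and the changes ran from -0.702 (Tmem119) to -0.137 (Sall1). Either could occur after loss of Usp7 from neurons.

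No other split drawn gave counts of genes, exon usage or intron clusters as large as the real split, which is counted among the splits. With 100 or 40 splits, the smallest share that can be reached is 1 of 100 or 1 of 40. The other splits mix the genotypes, so the genotype difference widens the spread within their groups and can lower their counts. Library order follows genotype, so the real split does not single out genotype. For genes, 1 of 100 splits of the 10 libraries gave as many as the real 3832, and the highest other gave 4 genes. For genes by exon usage 1 of 40 splits gave as many as 397 (highest other 18), for exon bins 1 of 40 as many as 980 (highest other 26), and for intron clusters 1 of 100 as many as 23 (highest other 5). For gene lists 4 of 100 splits gave at least 19 lists, and the highest other gave 20, more than the real split. The median of the other splits was 10 lists, so the number of lists that camera called does not by itself set the genotypes apart.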
